A study of Caenorhabditis elegans with 2 samples.

How the data were processed

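The series profiled the chromatin occupancy of UNC-130, a forkhead-domain transcription factor of the FoxD class, in the nematode Caenorhabditis elegans. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was run on whole animals of both sexes at the L1 larval stage. Per the labels, the animals carried an integrated transgene that expresses UNC-130 fused to enhanced green fluorescent protein (eGFP) in an unc-119 mutant background, and the fragment size range was 150 to 350 bp. The labels' description says that the immunoprecipitation was directed against the fusion protein, while the antibody label names unc-130, so whether untagged UNC-130 was also precipitated is open. They name 2 biological replicates of this single group. A control experiment that the labels mention was not analysed here. With one group and no control libraries, no contrast between conditions exists.

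The deposited files are peak lists in narrowPeak layout, given on the ce11 and ce10 builds of the genome. On each build there was a list for each replicate, a list called on both replicates pooled, and the list of pooled peaks that passed the authors' irreproducible discovery rate (IDR) threshold, called the optimal list below. Per the notes deposited with the files, the optimal list was derived from the pooled list and from both replicates' lists. The first 3 kinds of list are described by the deposited names as holding peaks and background, that is, candidate regions before thresholding. The aligner, the peak caller, their versions and the IDR cut-off are not given in the sources used here. Each peak carries a signal value that the authors' peak caller assigned. This deposited signal is the authors' own and was used only to rank, describe or filter peaks within 1 list. The deposited lists also hold a q-value on a −log10 scale, which was equal for all 2631 optimal peaks on ce11 (3.72) and was therefore not used for ranking. Both the pooled list and the list of replicate 1 hold exactly 30000 peaks, while that of replicate 2 holds 25234. The equal round number may be a limit set on the list, in which case shares of all candidate peaks depend on that limit. Nearly all peaks of a list share a width: 29987 of the pooled peaks are 250 bp wide, 29997 of replicate 1 are 220 bp and 25233 of replicate 2 are 276 bp. Of the optimal peaks, 2618 are 250 bp wide and 13 are narrower, all of them among the 43 highest. The files give no read counts, so the depth of each replicate is unknown and no interval based on reads could be computed. Intervals below treat peaks or genes as the counted units and cover counting error only.

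All coordinates are ce11 (the WBcel235 assembly) and count from 1. No deposited ce11 peak extended past the end of a chromosome of the WBcel235 reference. Gene models came from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. The ce10 lists were used only for their number and width of peaks, and no coordinate was converted between builds.

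The overlap of the replicates was the share of the 2631 peaks of replicate 1 with the highest signal that shared at least 1 bp with the 2631 highest of replicate 2. It was compared with 1000 random placements of the peaks of replicate 1 on the same chromosomes, in a one-sided permutation test. Rank agreement was Spearman's rho across optimal peaks that overlapped a peak of both replicates, with a two-sided permutation test of 100000 draws. To set values of the replicates side by side, each such peak was given its percentile of signal among these peaks within each replicate (100 is the highest), and the mean ± SD of the 2 percentiles is given. A summit was placed in the first that applied of these classes: promoter (within 500 bp of the 5′ end of a protein-coding gene), coding exon, untranslated region (UTR), intron, non-coding RNA gene, intergenic. Shares were compared with 1000 random placements on the same chromosome in a two-sided permutation test. Peaks per chromosome were compared with chromosome length by a chi-square statistic and 100000 multinomial draws, and the share of autosomal peaks in the middle 50% of each chromosome by an exact binomial test.

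The forkhead core TRTTKRY (R is A or G, K is G or T, Y is C or T) was searched on both strands within 50 bp of each summit. The share was compared with that in a 101 bp window centred 500 bp to one side of the same summit, the side being drawn at random once, in a two-sided exact McNemar test. The core was also ranked among all distinct permutations of its own columns. Each peak was assigned to the protein-coding gene whose 5′ end was nearest to the summit, if within 2000 bp, with ties given to both genes. For 24 gene lists, the share of genes with an assigned peak was compared with that of the other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists at 0.05. The lists were written from general knowledge of C. elegans, or, for gene families, by name pattern. Some share members. Shares carry 95% Wilson intervals, and a share of 0 carries the upper limit that 3 counts would give.

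The lists, tests and most alternatives were fixed before the data were examined. So was the rule for named genes. It takes unc-130, unc-129 and unc-119, the genes assigned to the 10 optimal peaks with the highest signal, and, for each list past the threshold, the 4 members with the highest peaks. It also takes all 8 genes tied to unc-130 by genetics and the 3 genes with the most assigned peaks, where ties were broken by the highest peak. The alternatives left out either replicate by taking the 2631 highest peaks of the other replicate's own list, halved or doubled the number of peaks, removed peaks near short non-coding RNA genes or near the transgene's loci, and varied distances, windows, flanks, motifs and the matching of genes. The replicates are named biological replicates in the labels, but each test above runs across peaks or genes, which are not independent replicates, so the p-values do not measure variation between animals.

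The procedures were tested on simulated data with known answers. A planted promoter share of 51.1% over 2631 sites was recovered as 50.7%, and a planted motif share of 40.4% as 40.5%. The motif was planted at random positions, without the difference in base composition between real summits and flanks. Only its share was checked there, not the McNemar test. A planted replicate overlap of 61.7% came back as 61.6%. A 4-fold higher share of genes with peaks was called in 95% of 100 draws for the body wall muscle list, 98% for the axon guidance list and 100% for the ribosomal protein list. Lists with no planted change were called in 0.43% of list draws. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used Matplotlib 3.10.9.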

Results

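The data were lists of UNC-130 peaks from 2 biological replicates of whole L1 larvae that express the eGFP-tagged protein. UNC-130 is known from genetics for roles in axon and cell migration through the TGF-beta ligand gene unc-129, and in the identity of sensory neurons and glia. The questions the design allows are where the tagged protein was found, how far the replicates found the same places, whether its sites hold a forkhead motif, and near which genes they lie. The optimal list held 2631 peaks on ce11, 8.77% of the 30000 pooled candidate peaks, a number that may be a set limit of the list, and equalled the top of the pooled list by signal. On ce10 the optimal list held 2623 peaks.

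The 10 optimal peaks with the highest pooled signal were all promoter peaks, with summits between 26 and 360 bp upstream of the 5′ end of their gene. They were assigned to rpl-3, ska-3, cdc-48.1, Y17G9B.5, hsr-9, rpl-12, mig-5, rpl-15, Y71H2AM.20 and wip-1. Of these, rpl-3, rpl-12 and rpl-15 encode proteins of the large ribosomal subunit, cdc-48.1 an AAA ATPase that extracts ubiquitinated proteins, mig-5 a Dishevelled protein of Wnt signalling and ska-3 a kinetochore-associated protein. The peak with the highest signal (218 in the pooled list) covered chromosome III 3867513 to 3867631, 272 bp upstream of rpl-3, and ranked 1 in replicate 1 and 3 in replicate 2. The peak of ska-3 (III 5679068 to 5679173) ranked 4 and 1. The peak of cdc-48.1 (II 10563514 to 10563631) ranked 2 and 19. The peak assigned to Y71H2AM.20 (III 2786001 to 2786090) lies inside the neighbouring gene cox-6B and ranked 3 and 130.

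The replicates shared most of their high peaks but ordered them differently. Of the 2631 highest peaks of replicate 1, 1530 (58.2%) overlapped one of the 2631 highest of replicate 2, against 1.33% ± 0.214 (SD, 1000 random placements). The permutation p of 0.000999 is the smallest that 1000 placements can give. Random positions ignore the preference of peaks for promoters given below. The test therefore shows more overlap than uniform placement gives, and does not separate shared sites from that preference. Among the 500 highest peaks of each replicate the overlap was lower, at 251 (50.2%), against 0.257% at random. Over all candidate peaks listed the overlap was 31.8%, against 12.3% at random, and this share depends on how far down each list was deposited. Of the optimal peaks, 2566 (97.5%) had an overlapping peak in both replicates' lists, and 1505 (57.2%) lay among the 2631 highest of both. These shares are not independent measures of agreement, because the optimal list was derived from these lists, which also hold background. Across those 2566 peaks, which are not independent replicates, Spearman's rho between the replicates' signal ranks was 0.24 (permutation p = 1e-05, the smallest that 100000 draws can give). Optimal peaks were selected on pooled signal, which leaves out peaks that were low in both replicates. Across the 9288 pooled candidate peaks found in both lists, a comparison chosen after the data were seen, rho was 0.60.

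**Figure D1:**
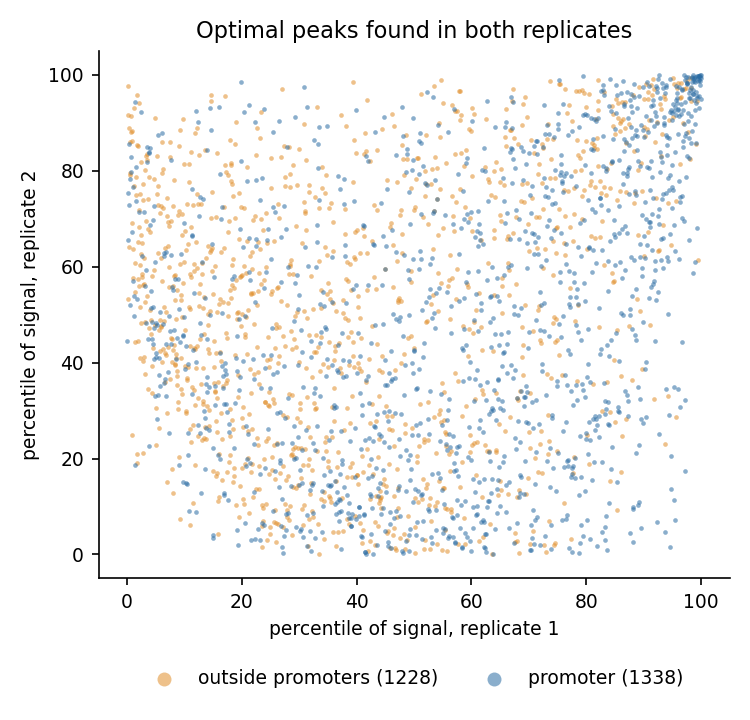
Percentile of signal of each of the 2566 optimal peaks found in both replicates, with replicate 1 on the x axis and replicate 2 on the y axis (100 is the highest); each point is a peak, blue for the 1338 promoter peaks and orange for the 1228 others. Promoter peaks crowd the upper right corner, while the overall rank correlation is 0.24.

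UNC-130 peaks lay mainly in promoters and rarely in coding exons outside them. Promoters held 1373 of the 2631 summits, or 52.2% (95% Wilson interval 50.3 to 54.1), which is 2.81 times the 18.6% ± 0.722 (SD) of random placements. Coding exons held 25 summits (0.95%), against 19.4% at random. Introns held 490 summits (18.6%, against 29.5%) and intergenic sequence 626 (23.8%, against 28.5%). Untranslated regions held 26 (0.988%, against 3.17%). Non-coding RNA genes held 91 summits (3.46%), 3.92 times the random share, and 114 optimal peaks lay in or within 100 bp of a tRNA gene. Each of the 6 shares differed from random placement (permutation p = 0.002, the smallest that 1000 placements give two-sided, and 0.002 after Benjamini-Hochberg adjustment over the 6). Promoter peaks were also the higher ones, with a median rank of 1084, against 1583 for intron peaks and 1529 for intergenic peaks. Among the 1997 peaks within 2000 bp of a 5′ end, 82.4% lay upstream of it and the median position was -171 bp.

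**Figure D2:**
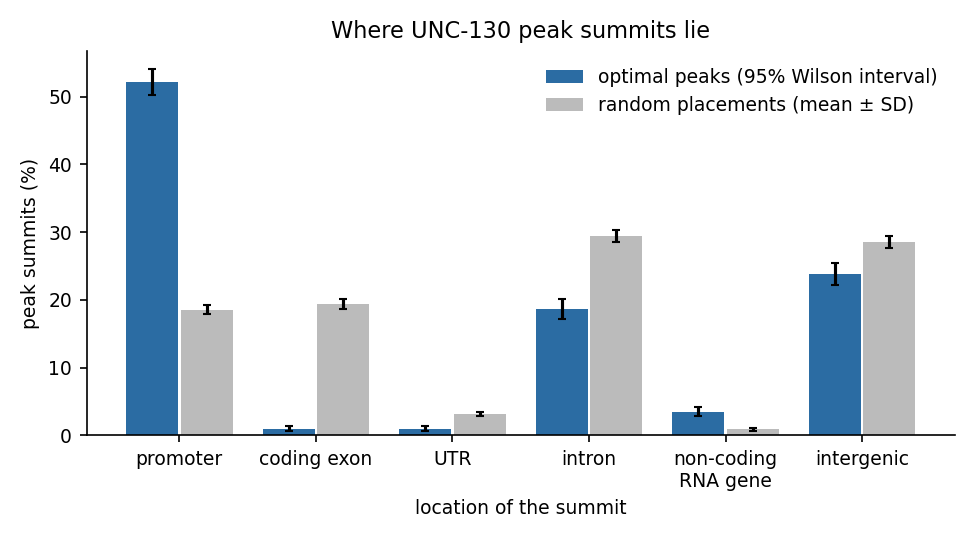
Share of the 2631 optimal peak summits in each class of location (blue, with 95% Wilson intervals) and the mean share over 1000 random placements on the same chromosomes (grey, with SD), on a y axis in percent. The promoter bar stands at 52.2% against 18.6% at random, and the coding exon bar at 0.95% against 19.4%.

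Along the genome, peaks were denser on chromosomes I and III and sparser on IV and V. Chromosome III held 428 peaks, 31.1 per Mb and 1.18 times the number expected from its length, and chromosome I held 459 (1.16 times). Chromosome V held 431 (20.6 per Mb, 0.785 times) and IV held 374 (0.815 times). Chromosomes II and X held 436 and 503, 1.09 and 1.08 times the expected numbers. The distribution differed from chromosome length (chi-square 69.7, permutation p = 1e-05, the smallest that 100000 draws can give). On the autosomes, 1364 of 2128 peaks (64.1%, interval 62.04 to 66.1) lay in the middle 50% of the chromosome (exact binomial test, two-sided, p = 4.71e-39). This share was highest on V (73.1%), and on the X chromosome it was 51.9% (47.5 to 56.2). Of the autosomal protein-coding genes, 55.7% lie in the same parts.

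Over all optimal peaks the degenerate forkhead core did not differ detectably from its flanks in the main test, which was not matched for base composition. Promoter peaks and the others differed from their flanks in opposite directions. TRTTKRY lay within 50 bp of the summit of 775 peaks (29.5%, interval 27.7 to 31.2), against 27.3% in the flanks. In the exact McNemar test against a flank drawn at random, 563 peaks had the core only at the summit and 516 only in the flank (p = 0.161). That test depended on the draw: 306 of 1000 draws of the flanks gave a p under 0.05, and an exact test on both flanks, added after the data were seen, gave p = 0.0483. Split by class after the data were seen, the core lay at 471 of 1373 promoter peaks (34.3%, interval 31.8 to 36.9), against 26.1% of their flanks (exact McNemar test p = 4.15e-05). Outside promoters it lay at 304 of 1258 peaks (24.2%, 21.9 to 26.6), less often than in the flanks (28.6%, exact McNemar test p = 0.0191). Within 100 bp of the summit, G and C made up 41.1% in promoter peaks and 44.8% in the others. Permuted motifs were not compared by class, so the lower share outside promoters cannot be told apart from base composition. The TRTTKRY result also depended on the replicate: without replicate 2 the share was 30.6%, against 26.5% in the flanks (exact McNemar test p = 0.00285), and without replicate 1 it was 27.6% at both. With its columns permuted the core ranked 7 of 420 by the difference between summit and flank. The core was 2.15 points more frequent at summits, while the median permuted motif was 9.17 points less frequent there. Summits were richer in G and C (42.9% within 100 bp against 36.5% at a distance of 500 bp). The main test therefore does not exclude an excess of the core over motifs of the same composition. The narrower TGTTTRC, chosen before the data were examined, lay at 280 summits (10.6%, interval 9.52 to 11.9), 3.59 times its share of 2.96% in the flanks (exact McNemar test p = 4.43e-29), and ranked 1 of its 210 column permutations. The canonical TGTTTAC was less common, at 2.24% of summits against 1.25% of flanks (exact McNemar test p = 0.00279). TGTTTGC, examined after the data were seen, accounted for most of the difference, at 8.59% against 1.71%. TGTTTRC was found at 15.1% of promoter peaks (interval 13.4 to 17.1, flanks 2.29%) and at 5.72% of the other peaks (4.57 to 7.15, flanks 3.70%), and these shares differed (Fisher's exact test, two-sided, p = 1.66e-15). In 4 equal groups of peaks from the highest to the lowest rank, its share was 11.9%, 12.3%, 10.3% and 8.07%. With GTAAACAA, a longer form, the shares were 0.760% and 0.589% (exact McNemar test p = 0.50).

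**Figure D3:**
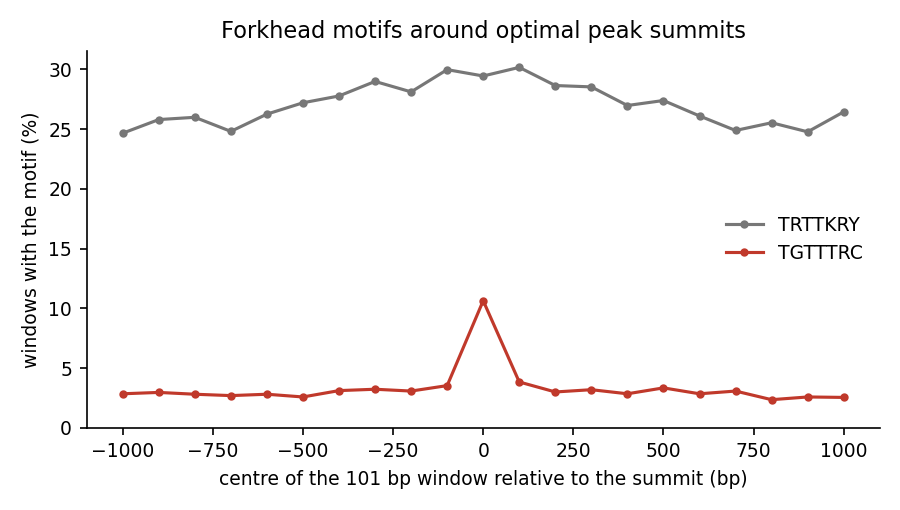
Share of windows of 50 bp to either side of their centre that contain TRTTKRY (grey) or TGTTTRC (red), in percent on the y axis, by the position of the window's centre relative to the summit, in bp on the x axis, over the 2631 optimal peaks. TGTTTRC stands at 10.6% at the summit and between 2.36% and 3.84% elsewhere, while TRTTKRY has no such peak.

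Peaks were assigned to 1864 protein-coding genes (9.33% of 19973), and 634 peaks lay farther than 2000 bp from any 5′ end. Most of these genes had 1 peak (1751), 93 had 2, and 20 had 3 or more. The gene mdl-1, which encodes a Mad-like basic helix-loop-helix protein, had the most, with 5 peaks between X 6741099 and 6744161. They lay 1127, 563 and 113 bp upstream of its 5′ end, in its intron and downstream of the gene. The DM-domain gene dmd-7 had 4, from V 6246607 to 6249023, of which 3 lay in annotated UTR sequence. Among 18 genes with 3 peaks, epg-9, an autophagy gene, had the highest, an intron peak at IV 2602060 to 2602309 that ranked 25 in the optimal list.

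Among the 24 lists, cytoplasmic ribosomal protein genes had the highest share of genes with a peak. Of the 78 members, 38 (48.7%, interval 37.9 to 59.6) had a peak, 5.31 times the 9.18% of other genes (Fisher's exact test with Benjamini-Hochberg adjustment over 24 lists, adjusted p = 3.89e-18). These genes had 39 peaks, of which 38 were promoter peaks (97.4%, against 68.2% of the other assigned peaks, Fisher's exact test, adjusted over 3 lists, p = 3.59e-05), and their median rank was 394. Besides rpl-3, the highest stood at rpl-12 (IV 13240552 to 13240801, 26 bp upstream), rpl-15 (IV 654811 to 655060, 360 bp upstream) and rpl-35 (III 7854563 to 7854812, 446 bp upstream). Their percentiles of signal were 99.3 ± 0.441, 99.7 ± 0.0827 and 99.2 ± 0.524 (SD, n = 2). When a peak was given to every gene with a 5′ end within 2000 bp, 71 of the 78 had one (6.05-fold). The peak of rpl-15 contained TGTTTRC within 50 bp of its summit, and those of rpl-3, rpl-12 and rpl-35 did not.

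Genes of the contractile apparatus and attachments of body wall muscle were a second group with many peaks. Of 39 genes, 13 (33.3%, interval 20.6 to 49.0) had at least 1 peak, 3.59 times the share of other genes (Fisher's exact test, adjusted p = 0.000187). These were act-1, atn-1, cpn-3, deb-1, mlc-2, mup-2, myo-3, pat-10, tnt-2, unc-27, unc-89, unc-97 and unc-112. The highest stood 1167 bp upstream of unc-97 (X 5591841 to 5592090, intergenic, percentile 63.6 ± 3.91, SD, n = 2), which encodes a LIM-domain protein of muscle attachments. The calponin gene cpn-3 had 3 peaks, the highest 658 bp upstream (I 3987157 to 3987406, percentile 40.4 ± 12.7). The troponin T gene mup-2 had a peak 347 bp upstream (X 6410449 to 6410698, percentile 38.3 ± 8.76). The troponin C gene pat-10 had one 135 bp downstream of its 5′ end (I 5020098 to 5020347, percentile 38.9 ± 13.8). These 17 peaks had a median rank of 1958. Of them, 8 (47.1%) were promoter peaks, against 68.9% of the other assigned peaks (Fisher's exact test, adjusted over 3 lists, p = 0.0655). In the upper 1315 optimal peaks alone, only 3 of the 39 genes had a peak (1.47-fold, Fisher's exact test, adjusted p = 0.713). Without replicate 1, in the list of replicate 2 alone, 20 had one (5.97-fold, Fisher's exact test, adjusted p = 5.72e-11). In the list of replicate 1 alone, 11 had one (2.99-fold, Fisher's exact test, adjusted p = 0.00439).

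Of 47 axon guidance genes, 12 (25.5%, interval 15.3 to 39.5) had a peak, 2.75 times the share of other genes (Fisher's exact test, adjusted p = 0.00477). The highest were at unc-115, unc-40, plx-1 and zig-3. The peak of unc-115, an actin-binding protein gene, lay 44 bp upstream (X 10146723 to 10146972, percentile 59.5 ± 38, SD, n = 2), and the replicates differed widely there. The netrin receptor gene unc-40 had a peak 295 bp upstream (I 5691673 to 5691922, percentile 59.3 ± 17.9), and the plexin gene plx-1 one 1444 bp upstream (IV 957952 to 958201, percentile 56.7 ± 0.772). The peak assigned to zig-3 lay downstream of the gene (X 7932535 to 7932784, 1910 bp from its 5′ end, percentile 68.3 ± 20.7). Only 4 of the 12 peaks were promoter peaks (33.3%, against 69.0% of the other assigned peaks, Fisher's exact test, adjusted over 3 lists, p = 0.0182). The call was lost under 6 of 15 alternatives, among them a limit of 1000 bp (1.86-fold, adjusted exact p = 0.264), and the list of replicate 1 alone (2.03-fold, adjusted exact p = 0.118).

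In 4 of the 24 lists the share of genes with a peak was lower than among other genes and passed the threshold. These were the lists of chemoreceptor, C-type lectin, col collagen and neuron identity genes. Of 1171 genes matched by the chemoreceptor name pattern, sr with further letters, 8 had a peak (0.683%, interval 0.347 to 1.34), 0.0692 times the share of other genes (Fisher's exact test, adjusted p = 2.65e-38). The pattern also takes in genes of other families, and 1 of the 8, srpa-72, encodes a signal recognition particle protein. With the names of 21 chemoreceptor families alone, an alternative added after the data were seen, 7 of 1116 genes had a peak (0.627%, interval 0.304 to 1.29, 0.0637-fold, Fisher's exact test, adjusted p = 5.08e-37). The highest were at srh-16, sri-5, srd-43 and sre-13, and 4 of the 8, including those at srd-43 and sre-13, lay in or within 100 bp of a short non-coding RNA gene. Of 240 C-type lectin genes, 1 (clec-149) had a peak (0.417%, interval 0.0736 to 2.32, adjusted exact p = 1.71e-08). Of 156 cuticle collagen genes named col, 5 (3.21%, interval 1.38 to 7.28) had a peak, 0.342 times the share of other genes (adjusted exact p = 0.0209). They were col-3, col-54, col-85, col-94 and col-181, and the peak assigned to col-94, the highest, lay in an intron of dhc-4. All but that of col-3 lay in or within 100 bp of a short non-coding RNA gene, and without such peaks 1 of 156 genes had one (0.0723-fold, adjusted exact p = 8.04e-05). The collagen call was lost under 6 of 15 alternatives, including without replicate 1 (0.589-fold, adjusted exact p = 0.241). None of 50 transcription factor genes of neuron identity had a peak, which allows a share of up to 6.0% (Fisher's exact test, adjusted p = 0.0445), and this call was lost under 11 of 15 alternatives. It was lost when genes were matched on the length of upstream intergenic sequence (permutation test with 10000 random lists, adjusted p = 0.0564) and without replicate 1 (0.230-fold, adjusted exact p = 0.232).

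The other lists did not pass the threshold. TGF-beta signalling had 5 of 22 genes with a peak (daf-5, kin-29, sma-2, sma-9 and tig-2, 2.44-fold, adjusted p = 0.145 by Fisher's exact test), and passed without replicate 1 (7 genes, adjusted p = 0.00774). Mesoderm and muscle transcription factors had 4 of 23 (hlh-1, unc-120, tbx-2 and sma-9, adjusted exact p = 0.323). Wnt signalling had 4 of 31, panneuronal genes 4 of 28, germline genes 5 of 46, glial genes 2 of 27, forkhead genes 2 of 15 (unc-130 and daf-16) and Hox genes and cofactors 1 of 12. Nuclear hormone receptor genes had 19 of 269, ceh homeobox genes 3 of 63, hlh genes 2 of 25 and histone genes 3 of 72. Hypodermis and seam genes had 1 of 37 and pharynx genes 1 of 29. Intestine genes and major sperm protein genes each had 0 of 31, which allows up to 9.68%. Chemoreceptor, lectin, collagen, histone and ribosomal genes have near-identical copies in places, so the assignment of single members is uncertain.

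**Figure D4:**
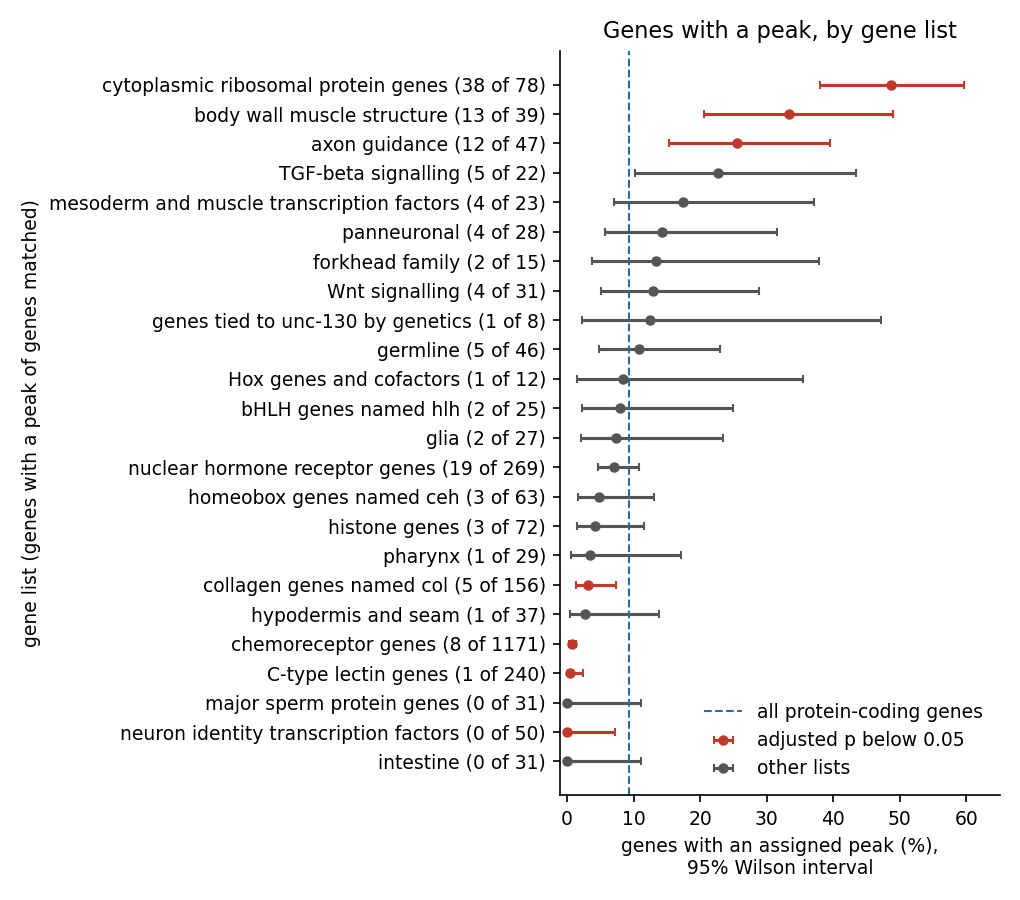
Share of the genes of each list with an assigned optimal peak, in percent on the x axis with 95% Wilson intervals, against the 9.33% of all protein-coding genes (dashed line); red points are lists with an adjusted p below 0.05. Ribosomal protein, body wall muscle and axon guidance genes lie to the right of the line, and chemoreceptor, C-type lectin, collagen and neuron identity genes to the left.

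Peaks were dense around unc-130 itself but no optimal peak was assigned to the other genes that genetics ties to it. The gene lies at II 11281966 to 11283959 on the forward strand, and 9 optimal peaks lay within 25 kb of its 5′ end, between 11275576 and 11293731. A median gene had 1, and 32 genes (0.160%) had as many. Windows of neighbouring genes overlap, so these 32 are not separate loci. The window of the neighbour cut-1, for example, holds the same 9 peaks. In the pooled list 38 peaks lay in the window of unc-130, against a median of 14, and the replicates had 40 and 31 there, against medians of 15 and 12. The highest peak, with a pooled signal of 96.0, stood at 11284748 to 11284997, downstream of the gene (rank 96, percentile 94.5 ± 4.68, SD, n = 2). The next stood 591 bp upstream at 11281250 to 11281499 (signal 83.5, rank 147, percentile 89.8 ± 9.48). Assigned peaks also lay in an intron (11283121 to 11283370, percentile 49.6 ± 19.3) and 1784 bp upstream (11280057 to 11280306, percentile 34.3 ± 48.1), where the percentile was 68.3 in replicate 1 and 0.234 in replicate 2. None of the 9 had TGTTTRC within 50 bp of its summit.

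Of the 8 genes tied to unc-130 by genetics, unc-130 alone had an assigned optimal peak. That share (12.5%, interval 2.24 to 47.1) was 1.34 times the 9.33% of other genes (Fisher's exact test, adjusted p = 0.686). With so few genes, the lack of peaks at the others cannot be told apart from the low share among all genes. The distances below are given without those of other genes for comparison. The nearest optimal summit lay 30313 bp from the 5′ end of unc-129, the TGF-beta family ligand gene. It lay 49885 bp from that of the LIM homeobox gene lin-11, 73626 bp from hlh-17, a glial helix-loop-helix gene, and 49538 bp from the homeobox gene mls-2. For the nuclear receptor gene odr-7 it was 7159 bp away, for the odorant receptor gene odr-10 24874 bp, and for unc-37, which encodes a Groucho corepressor, 11213 bp. Candidate peaks below the threshold lay closer, and each of these genes had such a peak of the pooled list within 2000 bp. One ranked 14535 of 30000 at 962 bp from unc-129, and one ranked 5219 at 201 bp from unc-37. Near unc-37 the nearest peak lay 155 bp away in replicate 2 but 5540 bp away in replicate 1. The pooled list includes background, and a median gene had 14 of its peaks within 25 kb, so such nearness does not show binding. The transgene marker unc-119 had no optimal peak within 2000 bp of its 5′ end, and 1 within 25 kb, the median of all genes.

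**Figure D5:**
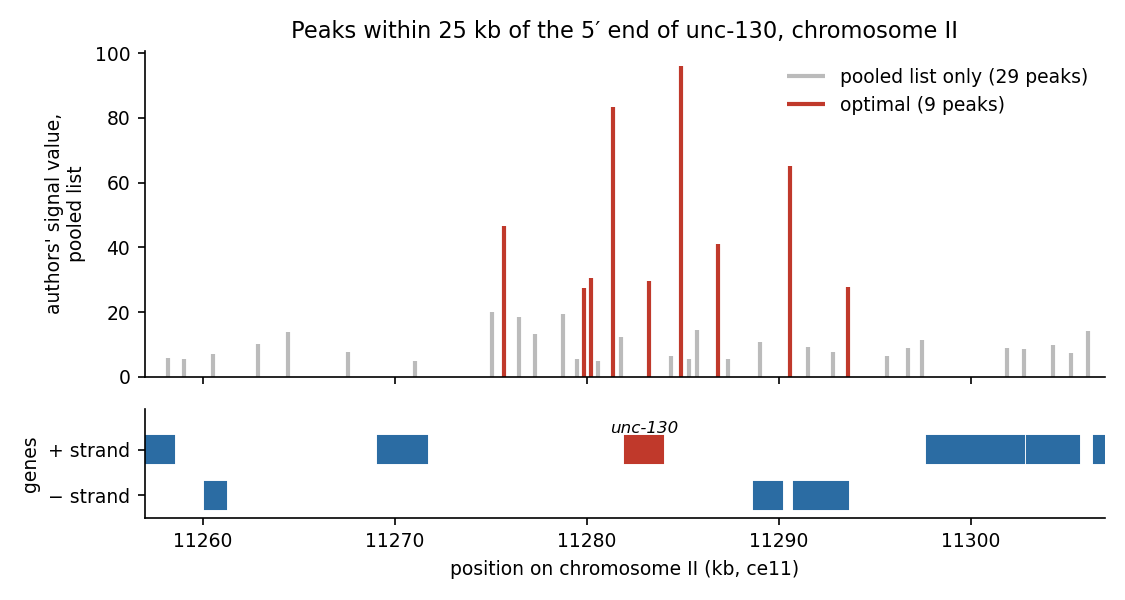
Peaks of the pooled list within 25 kb of the 5′ end of unc-130, with position on chromosome II in kb (ce11) on the x axis and the authors' signal value on the y axis; red lines are the 9 optimal peaks, grey lines the others, and boxes below are protein-coding genes by strand, unc-130 in red. The highest lines, at signals of 96.0 and 83.5, flank unc-130.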

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

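The shares of peaks in promoters and in the middle of the autosomes kept their direction and side of the threshold under every alternative run. So did replicate overlap and rank agreement. Promoter shares ranged from 37.7% (within 250 bp) to 62.8% (within 1000 bp) and rho from 0.17 to 0.60. The comparison of peaks per chromosome with chromosome length was not followed under the alternatives. The number of peaks, a count without a test, was 2623 on ce10 and 2628 on ce11 with overlapping intervals merged. Chemoreceptor genes stayed below other genes under all 16 alternatives, among them the chemoreceptor families alone (0.0637), ribosomal and body wall muscle genes kept their calls under 14 of 15, and C-type lectin genes under 14 of 15. The comparisons with both flanks, TGTTTGC, the top of both replicates, promoter or other peaks alone and the chemoreceptor families alone were chosen after the data were seen. Causes of the changes below were not tested, except that fewer peaks or genes in a setting also lower the power. Depth is unknown and could not be varied. No paired analysis was possible because there is 1 group.

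Without replicate 1 or 2 in turn, the TRTTKRY share ranged from 27.6% (-0.019 points from its flanks, no detectable difference, exact McNemar test p = 0.667) to 30.6% (above them, exact McNemar test p = 0.00285). Folds of the gene lists ranged from 1.92 to 3.68 for TGF-beta signalling, 1.17 to 2.14 for glia, 0 to 0.230 for neuron identity factors, 0.752 to 1.15 for germline, 0.404 to 0.589 for collagens, 2.03 to 3.21 for axon guidance, 0.704 to 2.31 for forkhead genes and 0.146 to 0.480 for histones. Without a change of side or call, they ranged from 2.99 to 5.97 for body wall muscle, 0 to 0.0951 for C-type lectins, 0.285 to 0.935 for hypodermis and seam, 1.02 to 2.24 for Wnt signalling and 0.422 to 0.922 for hlh genes. The TRTTKRY share passed its test against both flanks (29.5%), against flanks at 1000 or 2000 bp (29.5% at the summit, 25.6% and 25.7% in the flanks), within 25 bp (16.9%) and within 100 bp (50.02%). It also passed with TGTTTAC (2.24%), TGTTTRC (10.6%) and TGTTTGC (8.59%), and in promoter peaks alone (34.3%). In peaks outside promoters (24.2%) it was below its flanks.

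In the upper 1315 of the optimal peaks 3 lists were called instead of 7. Folds there were 1.47 for body wall muscle, 2.45 for axon guidance, 0 for neuron identity factors and 0.366 for collagens, which all lost their call. Uncalled lists changed side at 0.869 for TGF-beta signalling, 1.59 for Hox genes, 1.42 for glia and 0.683 for panneuronal genes. With 2 times as many pooled peaks, TGF-beta signalling (3.12) and major sperm protein genes (0) were called, neuron identity factors (0.248) and collagens (0.676) were not, and Hox genes (1.04) and germline (0.811) changed side. Without peaks at tRNA, rRNA, snoRNA or snRNA genes, neuron identity factors (0) lost their call, and the calls held for collagens at 0.0723 (1 gene instead of 5) and for genes of the chemoreceptor name pattern at 0.0366 (4 instead of 8, or 3 instead of 7 in the chemoreceptor families alone). Without peaks within 25 kb of unc-130 or unc-119, genes tied to unc-130 went to 0 and forkhead genes to 0.716. In the top of both replicates 4 lists were called: axon guidance (2.27), neuron identity factors (0) and collagens (0.339) were not, and Hox genes (1.48) and glia (1.31) changed side.

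With 5′ ends within 1000 bp, axon guidance (1.86) and neuron identity factors (0) lost their call and Hox genes reached 1.04. Within 5000 bp, neuron identity factors (0.372) and collagens (0.475) lost it and Hox genes reached 1.55. With every gene within 2000 bp, 71 ribosomal genes had a peak instead of 38 (70 when counted to the 3′ end), and body wall muscle stood at 2.18. There axon guidance (1.67) lost its call, intestine (0), ceh genes (0.310), nuclear hormone receptors (0.602) and major sperm protein genes (0) gained one, and genes tied to unc-130 (0.814) and forkhead genes (0.868) changed side. From 2000 bp upstream to the 3′ end, 11 lists were called. Among them ceh genes (0.304), nuclear hormone receptors (0.664), major sperm protein genes (0) and histones (0.355) were new, while genes tied to unc-130 (0.801) and Hox genes (1.6) changed side. Matched on upstream intergenic length, neuron identity factors (0) lost their call and histones (0.297) gained one. Without members of another list, neuron identity factors (0) lost theirs, and genes tied to unc-130 (0) and forkhead genes (0.893) changed side.

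With promoter peaks only, axon guidance (1.24) and neuron identity factors (0) lost their call. Genes tied to unc-130 (0), Wnt signalling (0.943), forkhead genes (0.974) and hlh genes (1.17) changed side. With peaks outside promoters only, 4 lists were called. Mesoderm and muscle transcription factors (6.09) gained a call, while neuron identity factors (0), collagens (0.444) and C-type lectins (0.143) lost theirs and ribosomal genes turned to 0.445. Changes of side among uncalled lists there were Hox genes (2.90), glia (2.58), pharynx (1.20), germline (0.756), ceh genes (1.11), nuclear hormone receptors (1.3) and hlh genes (2.79).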

Other observations

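All comparisons in this part were chosen after the peak lists had been examined, but 3 of the 4 tests of explanations had their outcomes stated before they were run. The fourth, on TGTTTRC as the source of ribosomal peaks, was stated when the share was already known. Among 175 gene families that share a name prefix and have at least 10 genes, 16 had a higher share of genes with a peak and 16 a lower one (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 175). Besides the ribosomal families, the higher ones included nuclear pore genes named npp (11 of 26, 4.55-fold, adjusted exact p = 0.000233), cyclophilin genes named cyn (8 of 16, 5.38-fold, adjusted exact p = 0.000794), proteasome regulatory genes named rpn (7 of 13, 5.79-fold, adjusted exact p = 0.00102), RNA polymerase II subunit genes named rpb (6 of 11, 5.86-fold, adjusted exact p = 0.00234), cyclin-dependent kinase genes named cdk (6 of 11, 5.86-fold, adjusted exact p = 0.00234) and translation initiation factor genes named eif (9 of 25, 3.87-fold, adjusted exact p = 0.00295). Names that group genes by mutant phenotype were also among them: lin (14 of 47, 3.21-fold, adjusted exact p = 0.00102), unc (21 of 94, 2.41-fold, adjusted exact p = 0.00169) and sup (5 of 11, 4.88-fold, adjusted exact p = 0.016). The unc genes with a peak include genes already counted above, so that share is not separate from those lists. Examples are unc-89 and unc-97 of body wall muscle, unc-40 and unc-115 of axon guidance, and unc-130 itself. The remaining higher families were mrpl, sec, cox, ints and tag. Among the lower ones were F-box genes named fbxa (0 of 170, adjusted exact p = 5.02e-06) and UDP-glucuronosyltransferase genes named ugt (0 of 67, adjusted exact p = 0.0189).

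Short sequences were frequent at summits, and some were more frequent in promoter peaks than in the others. Sequences of 7 bases, 8 per class of peak, were picked on the odd-ranked peaks and tested on the even-ranked ones against one flank at 500 bp. At 684 held-out promoter peaks, CAAACAC lay within 50 bp of 13.3% of summits and in 0.877% of flanks (exact McNemar test, adjusted over 16 sequences, p = 2.13e-19). It overlaps GCAAACA, the reverse complement of TGTTTGC, and whether these matches are forkhead sites was not tested. AACGCGC was found at 10.1% against 0.585% (adjusted exact p = 4.05e-16) and GTACGCA at 8.19% against 0.146% (adjusted exact p = 4.29e-15). At 631 held-out peaks outside promoters, CTCTCTC was found at 11.4% against 1.27% (adjusted exact p = 1.50e-13), AGAGAGA at 13.3% against 2.22% (adjusted exact p = 1.50e-13) and GAGACGC at 7.61% against 0.792% (adjusted exact p = 3.87e-10). In a direct comparison of the held-out classes (Fisher's exact test, two-sided, adjusted over 16 sequences), 7 of the 8 sequences picked in promoter peaks were more frequent there. CAAACAC, for example, lay at 3.49% of the peaks outside promoters (adjusted exact p = 7.63e-10). Some of these 7 overlap, such as AACGCGC and ACGCGCA, so they are not all separate findings. Of the 8 picked outside promoters, 1, AGAGAGA, was more frequent there (7.02% in promoter peaks, adjusted exact p = 0.000416). For CTCTCTC, whose reverse complement GAGAGAG overlaps AGAGAGA, a difference was not detected (8.48% in promoter peaks, adjusted exact p = 0.115). GAGACGC lay at 9.65% of promoter peaks, and a difference between the classes was not detected (adjusted exact p = 0.236).

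The replicates ordered promoter and other peaks differently. The median shift in percentile, replicate 1 minus replicate 2, was 8.18 points for 1338 promoter peaks and -8.32 for 1228 others, a difference of 16.5 points (bootstrap 95% interval 13.3 to 20.1). It was 10.9 for 271 peaks with TGTTTRC and 0 for 2295 without it. Of all 280 optimal peaks with TGTTTRC, 208 were promoter peaks, so a shift by motif was not separated from that of promoters, nor was it tested. By gene list the median shift was -28.8 for 16 peaks of body wall muscle genes, -10.8 for 12 of axon guidance genes and 0.857 for 39 of ribosomal protein genes. A bias by GC content that differs between the libraries is a technical candidate, since the shift correlated with the GC content of the peak (Spearman's rho -0.30 across peaks). Within 10 groups of peaks by GC content the difference was still 13.5 points (9.07 to 17.7), above the 8.25 that is 50% of the unadjusted difference, which argues against GC content as the main source. Differences in depth, fragment length or the mix of cells between the libraries stay open, and no biological explanation was tested since both replicates belong to 1 group.

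The cluster of 9 optimal peaks around unc-130 may come from extra copies of the locus on the transgene, which would raise reads over all of it, exons included, or from UNC-130 bound at its own gene. In the window, 8 of 38 pooled candidate peaks (21.1%, Wilson interval 11.1 to 36.3) lay in coding exons, against 29% in the rest of the list, while 22.5% of the bases in the window are coding. This comparison cannot decide, because even extra copies would not be expected to put more peaks in coding exons than the coding share of the window, which is below that 29%. Both explanations stay open. At unc-119, 14 pooled peaks lay within 25 kb, the median of all genes, but the labels do not say how much of unc-119 the transgene carries. Binding at the gene itself was not tested, and the control library that bears on it was not analysed here.

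The high rank of ribosomal protein promoters could reflect promoter signal that needs no forkhead site. TGTTTRC lay at 4 of their 38 promoter peaks (10.5%, Wilson interval 4.17 to 24.1) and at 15.3% of 1335 other promoter peaks, and the shares did not differ detectably (Fisher's exact test, two-sided, p = 0.645). That comparison cannot decide, because signal of the same kind at all promoters would leave the shares equal. The share itself argues against binding through TGTTTRC at most of these peaks: its upper limit of 24.1% is below 50% (34 of the 38 lack the motif). The 50% limit was set when the share was known. At 15.3%, the other promoter peaks also lie below it, so this is not particular to ribosomal protein promoters. The degenerate core TRTTKRY lay at 8 of the 38 (21.1%), against 34.7% of the other promoter peaks (Fisher's exact test, two-sided, p = 0.0855). In the flanks of all promoter peaks it lay at 26.1%, and no excess over either share was seen. The flanks of the ribosomal peaks themselves were not compared, so an excess over those is not excluded. Binding through other sequences, or through other proteins, stays open beside such promoter signal. Peak lists of other factors, which would show whether these promoters are shared by many proteins, were not used here.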
